A study of Zea mays with 21 samples.

How the data were processed

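RNA was measured in leaf and endosperm of WT and zb10 maize, with 3 libraries in each of 7 groups. Per the labels' protocols, RNA was extracted with a column kit and made into libraries with a SMARTer mRNA kit. Values were used as the raw counts per gene that the authors deposited, in 1 table of 50142 gene IDs, of which 39323 carry reference-style IDs and 10819 are newGene loci; 6923 had no count in any library. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and whether reads shared by near-identical copies were split is not known. Column names of the table call the mutant zb9 where the labels say zb10, and the younger leaf 3L where the labels say V4; each column was matched to the only labelled group that fits it, and the WT columns of the younger leaf were matched to V4 because no other WT leaf group remained. No column was left without a sample. Replicates are described in the series design as biological, and p-values measure the spread between those libraries. No 2 replicates of a group agreed within sampling noise.

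Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, Benjamini-Hochberg adjusted p under 0.05). V4 libraries were fitted together, and V9 and endosperm apart; interaction contrasts were fitted over the groups involved. CPM (counts scaled to library size) are scaled by TMM over all libraries. Standard errors are those implied by the F-test. Library totals of 28237880 to 123050963 counts set the precision; bounds from a floor of 3 counts cover counting error only, because reads without molecular identifiers are not independent molecules. The share of each gene group is a percent of a library's total counts, with leaf abundance taken from V9 leaf for every library.

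Before the data were examined, the tests, the alternatives and lists of carotenoid, oxidase and other pathways were fixed. None of the IDs matched the reference table (0 of 50142, the maize B73 NAM assembly), so those lists, the look-up of the mutated gene and the planned set tests were not used here. The fallback fixed beforehand was to print the 2 highest and 2 lowest IDs per comparison, read here with the limits fixed for named genes: past the threshold, groups that do not overlap, and a mean of log2(CPM + 0.5) over the compared libraries of at least 2. This mean leaves out genes near 0 in 1 group, among them the gene of lowest p in endosperm (mean 1.30), and only 1 lower ID met the limits there. The gene groups were built after the table was seen. Leaf abundance came from leaf libraries other than those compared (V9 leaf for V4 comparisons, V4 leaf for V9 and endosperm), and endosperm abundance was the mean over both genotypes, so that in the endosperm comparison groups defined with it rest on the libraries compared. The groups were leaf-enriched, endosperm-enriched (at least 16-fold, at least 10 CPM), shared (within 4-fold), the top 100 transcripts of each tissue, and new loci. The lists of genes higher or lower in the white section were chosen on the V4 libraries. Set tests used camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated one. DESeq2 1.42.0 was run as an alternative. Other alternatives covered scaling, filters, a replicate block, removal of the 50 most abundant genes, the libraries in the fit and leaving out each library.

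Replicate numbers may pair the white and green sections at V4: deviations from the group means correlated at 0.19, 0.18 and 0.41 across genes for the same numbers, each higher than with any other number. The pairing comes from these values, since the labels only number the samples. With 3 libraries per section few matchings are possible, so chance can give it. The main fit did not use the pairing, and a replicate block was run as an alternative.

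The fits were tested on simulated counts with 200 changed genes, drawn from the real means, library sizes and spread. For V4 white against WT 51% of 2-fold and 71% of 4-fold changes were recovered, with 13 false calls among 26254 genes. For endosperm the shares were 42% and 73%, with 11 false calls among 24597. As 100 genes were changed at each fold, false calls exceeded 0.05 of the calls made in both comparisons, above the adjusted p threshold. They stayed under 0.05 for green against WT (6 false calls, 51% and 75% recovered). The same held for endosperm minus V9 (2 false calls, 6% and 45% recovered). In the other comparisons simulated they exceeded 0.05. Each share rests on few false calls. Far more than 200 genes were called in the real white-section comparisons (8450 against WT and 6529 against green). Recovery and the share of false calls depend on how many genes change, so the simulated shares need not hold there.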

Results

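Transcript counts were measured in leaves and endosperm of wild-type (WT) maize and of the zebra-leaf mutant zb10, which the series describes as a loss of function in ZmPTOX, the plastid terminal oxidase. This enzyme oxidises plastoquinol in plastids and takes part in carotenoid desaturation. The 21 libraries form 7 groups of 3: WT leaf, the white section and the green section of zb10 leaves at the V4 stage (the 4th-leaf stage per the series design, although the count columns matched to these groups are named 3L), WT and zb10 leaf at the V9 stage (the 9th-leaf stage), and WT and zb10 endosperm at 16 days after pollination. Library totals ran from 28237880 to 53092962 counts, except for WT V9 replicate 1 with 123050963. The stated purpose was to compare carotenoid pathway and alternative oxidase genes, but the files do not pair gene IDs with names and 0 of 50142 IDs matched the reference table used here, so the mutated gene and both families were not analysed here by name. Genes are therefore given by ID, and gene groups were defined from where the transcripts were abundant.

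The white section of the zb10 leaf differed widely from WT leaf at V4. Of 26871 genes tested, 4465 were higher and 3985 lower in the white section, of which 1722 and 1476 changed more than 2-fold. Zm00001d011420 had 0 counts in the WT libraries and 37.4 ± 6.19 CPM (counts scaled to library size; SD, n = 3) in the white section, at least 1370-fold higher by a floor of 3 counts over the group. Zm00001d042453 stood at 144 ± 31 CPM against 0.0828 ± 0.102 in WT (log2 fold change 10.74, SE 0.4, adjusted p = 2.5e-07). Zm00001d020008 fell from 35.2 ± 5.7 to 0.67 ± 0.331 CPM (log2 fold change -5.70, SE 0.35, adjusted p = 4.6e-06), and Zm00001d003494 from 27.6 ± 16.1 to 0.223 ± 0.168 CPM (log2 fold change -6.90, SE 1.32, adjusted p = 0.0069).

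Among 1942 tested leaf-enriched genes, defined as at least 16-fold more abundant in V9 leaf than in endosperm, 331 were higher and 508 lower in the white section than in WT, with a median log2 fold change of -0.21. The 100 most abundant V9 leaf transcripts included 11 higher and 18 lower members, with a median of -0.41. The preset-correlation set test placed both groups below other genes (adjusted p = 0.01 and 0.016), and neither passed with an estimated correlation (adjusted p = 0.8 for each). Leaf-enriched genes held 39.7 ± 1.02% of counts in WT V4 leaf (SD, n = 3) and 34.7 ± 4.65% in the white section. The ranges did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. White section replicate 3 had the lowest share, 29.3%, and its 50 most abundant genes held 11.9% of its counts against 17.3% and 17.4% in the other white libraries. Among 7287 tested genes of similar abundance in leaf and endosperm, 1509 were higher and 1316 lower, with a median of 0.03. With library size as the only scaling the median of all genes moved to 0.14, and 69.4% of calls were higher against 52.8% with the scaling used.

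**Figure D1:**
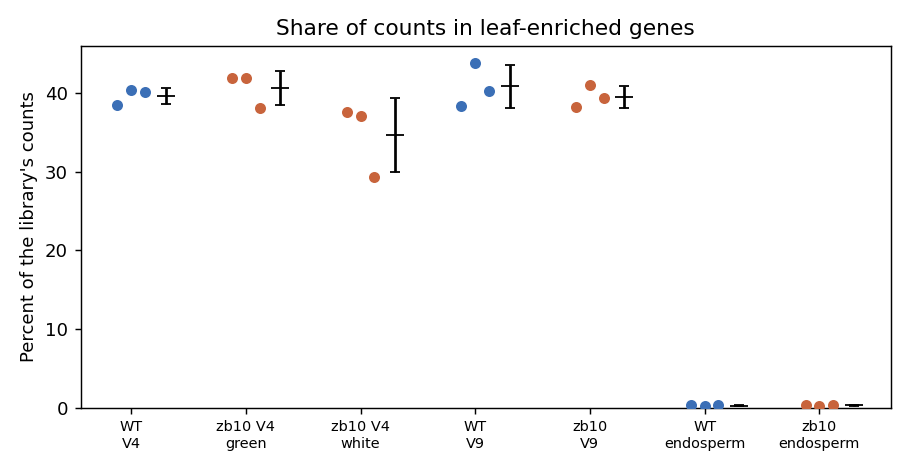
Percent of each library's counts (vertical axis) that fell in leaf-enriched genes, by group (horizontal axis); points are libraries, and the black mark and bar give the mean and SD of 3. White-section libraries had a mean of 34.7%, against 39.7% in WT and 40.6% in the green section at V4. The group was defined on the V9 leaf and endosperm libraries, so the gap between those points follows from the definition.

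The green section of zb10 leaves differed from WT in 209 genes, 117 higher and 92 lower, of which 68 and 52 changed more than 2-fold. Zm00001d042453 was again far above WT, at 153 ± 8.58 CPM (SD, n = 3; log2 fold change 10.81, SE 0.4, adjusted p = 1.9e-06). Zm00001d001771 rose from 1.73 ± 0.558 to 11.2 ± 2.28 CPM (log2 fold change 2.69, SE 0.26, adjusted p = 0.0015). Zm00001d001909 fell from 61.5 ± 5.08 to 7.36 ± 0.376 CPM (log2 fold change -3.06, SE 0.1, adjusted p = 2.4e-07), and Zm00001d052985 from 20.2 ± 2.84 to 1.21 ± 0.393 CPM (log2 fold change -4.05, SE 0.23, adjusted p = 1.5e-05). Leaf-enriched genes had a median log2 fold change of 0.03, with 28 higher and 19 lower of 1942. Unannotated loci (IDs of the newGene form) counted 24 higher and 4 lower of 3818 (adjusted p = 0.032 with the preset correlation; adjusted p = 0.91 with an estimated correlation). The number of green-section calls was sensitive to the samples in the fit: it ranged from 44 to 104 when 1 library was left out, was 493 with the compared groups alone, 77 with all 21 libraries and 874 with DESeq2.

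Within zb10 leaves, the white section had 3615 genes higher and 2914 lower than the green section. Zm00001d028750 stood at 121 ± 28.7 CPM in the white and 0.121 ± 0.209 in the green section (log2 fold change 10.10, SE 0.78, adjusted p = 0.00013), and Zm00001d021804 at 41.6 ± 1.43 and 0.303 ± 0.113 CPM (log2 fold change 7.07, SE 0.24, adjusted p = 1.1e-07). Zm00001d015053 was lower in the white section, at 5.09 ± 3.33 against 41.0 ± 12.5 CPM (log2 fold change -3, SE 0.55, adjusted p = 0.0069). Zm00001d011079 was at 2.11 ± 0.803 against 18.8 ± 21.4 CPM (log2 fold change -3.12, SE 0.92, adjusted p = 0.048), and the call was lost in 9 of the 15 alternatives that gave an adjusted p (0.054 to 0.15; DESeq2 gave none), among them the replicate block (0.089) and leaving out any white library or green replicate 3. Without green replicate 1 its log2 fold change was -1.60. Leaf-enriched genes were 234 higher and 421 lower of 1942, with a median of -0.23 (adjusted p = 0.00066; adjusted p = 0.7 with an estimated correlation). The top 100 leaf transcripts had 5 higher and 16 lower, with a median of -0.49 (adjusted p = 0.00015; adjusted p = 0.7 with an estimated correlation); with the 2 sections alone and the replicate block, 6 were higher and 32 lower. With library size alone the median of all genes was 0.119, and 73.7% of calls were higher against 55.4%.

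Because both zb10 sections were compared with the same 3 WT libraries, their fold changes are correlated by construction. Across 26871 genes the correlation between white-section and green-section changes was 0.549, where unchanged simulated groups gave a mean of 0.502 over 20 simulations. The covariance was 0.422, against 0.0936 simulated. The same sign was seen in 66.2% of genes, within the 66% to 67.3% of the simulations. Those simulations left both sections unchanged and held no likeness between white and green libraries of the same number. The real white section changed widely, so they do not give the values for a changed white beside an unchanged green section. Whether the agreement exceeds that stays open. Of the 117 genes higher in the green section 95 were also higher in the white section, and of the 92 lower 85 were also lower; independent lists would share 19.4 and 13.6. Part of the excess may come from the shared controls, which could not be split. Genes called higher in white than in both WT and green, with green against WT not called, numbered 3049, and those lower 2256. A missing call does not show that green was unchanged, since 51% of simulated 2-fold changes were recovered for green against WT.

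**Figure D2:**
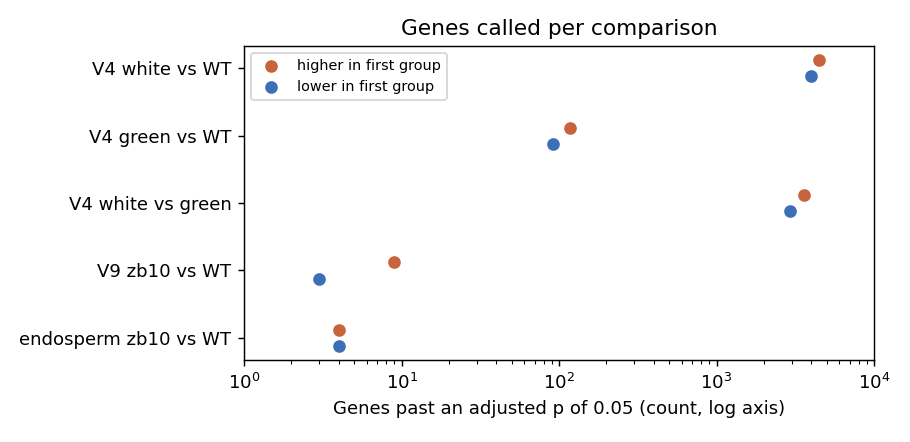
Genes past an adjusted p of 0.05 in each comparison (log axis), with those higher in the first-named group in orange and lower in blue. The white section of the V4 leaf gives 4465 and 3985, the endosperm 4 and 4.

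At V9, zb10 leaf differed from WT in 12 of 26105 genes, 9 higher and 3 lower. Zm00001d042453 was at 145 ± 20.4 CPM against 0.188 ± 0.162 (SD, n = 3; log2 fold change 10.02, SE 0.52, adjusted p = 0.0016), and Zea_mays_newGene_19852 at 21 ± 3.47 against 0.731 ± 0.23 CPM (log2 fold change 4.81, SE 0.28, adjusted p = 0.0021). Zm00001d001909 fell from 70.2 ± 13.5 to 15 ± 1.37 CPM (log2 fold change -2.22, SE 0.18, adjusted p = 0.01), and Zm00001d052985 from 17.3 ± 3.15 to 2.84 ± 0.807 CPM (log2 fold change -2.60, SE 0.26, adjusted p = 0.026). The call of Zm00001d001909 was lost on leaving out WT replicate 3 or any zb10 replicate (adjusted p of 0.069 to 0.13) and that of Zm00001d052985 on leaving out any library but WT replicate 2 (adjusted p of 0.052 to 0.33), with log2 fold changes of -2.15 to -2.84. Leaf-enriched genes, of which 2043 were tested, had a median log2 fold change of -0.07. The groups of genes higher and lower in the white section at V4 had medians of 0.04 and -0.03 at V9. New loci had a median of 0.18 (adjusted p = 1e-04 with the preset correlation; adjusted p = 0.41 with an estimated correlation). At an unadjusted p under 0.05 there were 1831 genes, against 1305 by chance. DESeq2 called 230 genes, 90 higher and 140 lower, and without WT V9 replicate 2 edgeR called 168, 29 higher and 139 lower, so the balance of calls turned in both. In simulated data with the V9 spread, 17% of 2-fold and 71% of 4-fold changes were recovered.

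**Figure D3:**
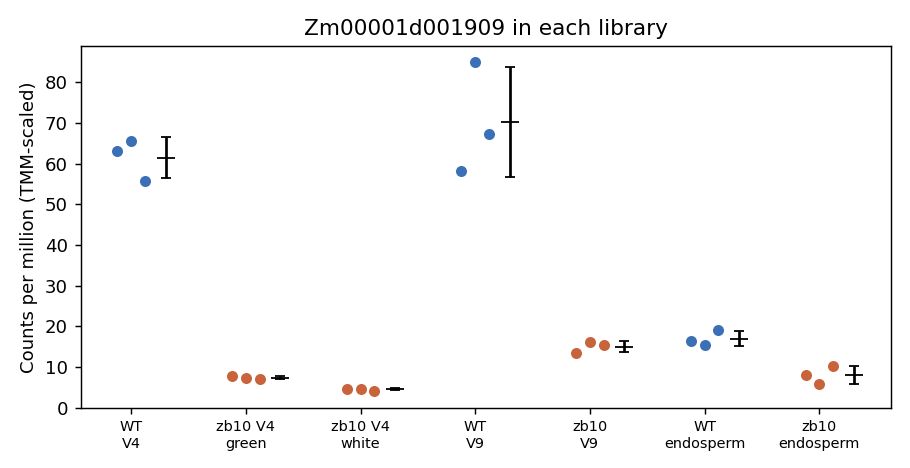
CPM of Zm00001d001909 (vertical axis) in each of the 21 libraries, by group; points are libraries, and the black mark and bar give the mean and SD of 3. Green-section libraries averaged 7.36 CPM against 61.5 in WT at V4, and zb10 leaf 15 against 70.2 at V9.

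Across leaf, 8 IDs passed in all 3 comparisons with WT in the same direction, 6 higher and 2 lower. The 2 lower were Zm00001d001909, which was at 4.53 ± 0.266 CPM in the white section (SD, n = 3; log2 fold change -3.75, SE 0.11, adjusted p = 2.1e-08), and Zm00001d052985, at 1.31 ± 0.0142 CPM (log2 fold change -3.93, SE 0.22, adjusted p = 1.6e-06). Of the 8, Zm00001d042453 and Zm00001d001771 were among the higher. The V9 call of Zm00001d001771 (log2 fold change 2.67, adjusted p = 0.047) was lost in 9 of 15 alternatives, 5 of them fits with 1 library left out (every one but WT replicate 2), with adjusted p of 0.051 to 0.29. The call of Zm00001d001804 in the green section (log2 fold change 1.75, adjusted p = 0.038) was lost on leaving out any of the 6 libraries (adjusted p of 0.062 to 0.15). All 3 calls were kept in every alternative for 2 of the 8 IDs, Zm00001d042453 and Zea_mays_newGene_19853, and on leaving out each library for 3. These 8 were chosen after their values were seen.

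The endosperm of zb10 differed from that of WT in 8 of 25366 genes, 4 higher and 4 lower. Of the 8, 7 are new loci, which made up 4004 of the genes tested. Another split of the same libraries, which mixed the genotypes, also gave 8 genes. Zea_mays_newGene_10916 was at 38.6 ± 9.58 CPM against 6.62 ± 1.33 in WT (SD, n = 3; log2 fold change 2.58, SE 0.21, adjusted p = 0.0086). Zea_mays_newGene_20647 was at 14.0 ± 2.21 against 3.86 ± 0.367 CPM (log2 fold change 1.90, SE 0.17, adjusted p = 0.0086), and Zea_mays_newGene_5341 at 5.55 ± 1.46 against 27.2 ± 5.23 CPM (log2 fold change -2.26, SE 0.23, adjusted p = 0.027). The call of Zea_mays_newGene_10916 was lost without WT replicate 1 or 3 (adjusted p = 0.054 and 0.14). That of Zea_mays_newGene_20647 was lost without any WT replicate (adjusted p of 0.058 to 0.074). That of Zea_mays_newGene_5341 was lost on leaving out any library but zb10 replicate 2 (adjusted p of 0.053 to 0.096). Zea_mays_newGene_17609, chosen after its values were seen because it had the lowest p, had 246, 374 and 471 counts in the WT libraries and 0, 2 and 0 in those of zb10, a ratio of 473 (95% counting interval 131 to 3900, adjusted p = 0.0049); without WT replicate 3 its adjusted p was 0.06. Zm00001d001909 was at 8.08 ± 2.13 against 17.0 ± 1.82 CPM and did not pass (log2 fold change -1.03, SE 0.19, adjusted p = 0.34), although it passed with all 21 libraries in the edgeR fit (adjusted p = 0.011) and with DESeq2 (adjusted p = 0.0015). Of the 8 IDs called in all leaf comparisons 7 were tested in endosperm, and 5 of these had the same sign as in leaf. Among the 5, Zm00001d052985 had 13 counts in zb10 and 145 in WT (log2 fold change -3.26, adjusted p = 0.49). It passed with DESeq2 (adjusted p = 0.011) and with all 21 libraries in the edgeR fit (adjusted p = 0.0046). The IDs of opposite sign were Zea_mays_newGene_19852, with a log2 fold change of -0.99 (adjusted p = 0.46, and 0.012 with DESeq2) against 3.93 to 4.81 in leaf, and Zea_mays_newGene_19853, with -0.29 (adjusted p = 0.93). Zm00001d042453 had 4, 6 and 0 counts in the WT endosperm libraries and 19597, 0 and 10001 in those of zb10, and was left out by the count filter. The 100 most abundant endosperm transcripts, ranked on the same endosperm libraries over both genotypes, had a median log2 fold change of -0.11 (adjusted p = 4.6e-05; adjusted p = 0.36 with an estimated correlation). Top leaf transcripts had a median of -0.43 over 90 tested (adjusted p = 2e-04; adjusted p = 0.57 with an estimated correlation), in endosperm libraries whose trace level of leaf transcripts ran from 10.8 to 121 CPM. With a term for the 2 sets of libraries with high and low traces, added after the data were seen, 1 gene was higher and 1 lower. The call of Zea_mays_newGene_17609 was kept with that term (adjusted p = 0.011), and the other 3 loci named lost theirs (adjusted p of 0.056 to 0.058) with fold changes of 2.58, 1.92 and -2.33 on the log2 scale. At an unadjusted p under 0.05 there were 1395 genes, against 1268 by chance. DESeq2 called 117 genes, and leaving out WT replicate 1 or 3 left 1 or 0.

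The difference of the mutant effect itself was tested across stages and tissues. The V9 labels name no leaf section, so contrasts of V9 with a V4 section change stage and section sampled together. Between V9 and the white section at V4, 3220 of 28513 genes had effects that differed, 1371 higher and 1849 lower at V9 (42.6% higher, and 30.7% with library size alone). Between V9 and the green section 1 gene passed, and between endosperm and V9 12 of 30640 passed, 3 higher and 9 lower in endosperm (25% higher, and 51.3% of 191 calls with DESeq2). At an unadjusted p under 0.05 there were 2689 genes for V9 against green, with 1426 by chance. Across the comparisons that share no library, V4 green and V9 both held 6 genes higher and 2 lower, where independent lists would share 0.034 and 0.011. White against WT and V9 shared 7 higher and 3 lower, where independent lists would share 1.4 and 0.46. Endosperm shared 0 higher and 0 lower with V9, 1 and 0 with green, and 2 and 1 with white against WT.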

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

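Tests of WT V9 replicates 1 and 2, of the leaf-enriched share of endosperm calls, of the direction of calls in an ID range, of windows of ID numbers, of that range without V9 calls, of the rise of stage-specific genes with leaf traces and of splits by which labels they keep were chosen after the result was seen. The mutant effect differed between V9 and the white section at V4 in 3220 genes, between V9 and the green section in 1 gene and between endosperm and V9 in 12 genes, each by an interaction contrast. Random splits of the libraries within each stage or tissue gave as many genes in 5, 31 and 11 of 100 splits, the real one included, for the white section, the green section and endosperm in turn; the highest other splits gave 5155, 75 and 81 genes. None of these shares is under 0.05, so the splits do not exclude chance for any of the counts. For the white section the 4 other splits that gave as many kept the V4 libraries as labelled, and so kept the difference between white section and WT. The 10 splits of that kind gave 2506 to 5155 genes with the V9 libraries mixed. The 89 that mixed the V4 libraries gave at most 3. Mixing them removes the difference between white section and WT, so low counts were fixed in advance there and exclude nothing. The count of 3220 thus rests on the V4 difference, and the splits do not show that the V9 genotypes add to it. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Split counts of the real and highest other grouping were 8450 and 1 for white against WT, 209 and 0 for green against WT, 6529 and 1 for white against green, 12 and 3 at V9, and 8 and 8 in endosperm. For white against green, the 3 other splits that part all pairs gave at most 1 gene.

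The endosperm split that gave 8 genes, so that 2 of 10 did, groups the 3 libraries with high traces of leaf transcripts (WT replicates 1 and 3, zb10 replicate 1, at 109, 121 and 102 CPM summed over 62 genes, as a share of the library total) against the others (10.8, 14.1 and 22). Of the 8 genes called between genotypes 0 were leaf-enriched by V4 leaf, a group of 1207 of the 25366 genes tested. Few of 8 would fall in it by that share alone, so this argues only weakly against V4 leaf RNA as the direct source of those calls. Genes enriched in V9 leaf were not counted. Genes specific to V4 and to V9 leaf stood at ratios of 1.01 and 1.72 between high- and low-trace libraries, but the bounds set beforehand (1.5 and 3) were set too high, since carry-over at the level of the traces would give only 1.36 and 1.69. On that scale V4-specific genes would rise by 9.7 CPM and rose by 0.37, at most 6 between any 2 libraries, which argues against V4 leaf as the source; V9-specific genes would rise by 9.9 and rose by 10, so V9 leaf stays open as a source. With a term for these sets 1 gene was higher and 1 lower, and Zea_mays_newGene_10916 went from 2.58 (SE 0.21, adjusted p = 0.0086) to 2.58 (SE 0.23, adjusted p = 0.056), with the fold unchanged, a wider error and 1 residual degree of freedom fewer. The genotype effect in endosperm remains untested beyond these libraries.

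At V9 few genes were called. Thinning WT replicate 1 (123050963 counts) to the median total of the others gave 13 genes, so its depth is not the source of the low count. Leaving out WT replicate 2 gave 168 genes, against 5 to 7 without any other library, so that 1 library may set the spread at V9; what sets it apart was not tested. As the biological alternative, the mutant effect differed from that in the white section in 3220 genes by the interaction contrast. Splits that kept the V4 labels and mixed the V9 libraries gave 2506 to 5155 genes, so the count does not measure an effect at V9. The V9 labels name no section, so that contrast cannot part stage from leaf section. The lists of genes higher and lower in the white section, chosen on the V4 libraries, had V9 medians of 0.04 and -0.03. Measured changes of those genes were thus smaller at V9, to which choosing the lists on V4 values can contribute. A smaller effect than in the green section stays open.

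A range of ID numbers from 1771 to 2338 was drawn around the 4 V9 calls of lowest ID number, so V9 calls cannot test it. Other V9 calls with reference-style IDs lay outside it, among them Zm00001d042453 and Zm00001d052985. In the green section 9 genes in the range were called, and 4 of them were those V9 calls. Without these, 5 of 299 were called (1.67% against 0.747% outside, Fisher's exact two-sided p = 0.078). An unadjusted p under 0.05 was found for 13% against 12.5% outside (Fisher's exact two-sided p = 0.79). Neither measure passed 0.05 in the green section, and 5 calls are too few to decide. In the white section, which shares its WT libraries with the green, 52.8% had an unadjusted p under 0.05 against 43.7% outside (Fisher's exact two-sided p = 0.0018). White against green, both zb10, gave 43.6% of 303 genes against 37.8% outside with the V9 calls included (Fisher's exact two-sided p = 0.043). The white-section excess therefore need not come from a difference in background between the genotypes. In the endosperm, which did not define the range, 10% of 280 genes had an unadjusted p under 0.05 against 5.33% outside (Fisher's exact two-sided p = 0.0019, and p = 0.0065 without the V9 calls). Of 1031 windows of 568 ID numbers 4 were as high. The windows start every 50 numbers and so overlap, and those over the range itself were included, so they are not independent. The endosperm values would be consistent with linked background carried with the mutation, if ID numbers follow map position, which is not stated in the sources used here; genes in a range are not independent. Reads of a variant allele that fail to align cannot be told apart from it: 7 of the 9 called in the green section were higher, but the labels do not say which genotype differs from the reference, so either direction is open.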

How the results depend on the processing

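The leaf trace term, the thinned library and the 2 zb10 sections alone with a block were added after the data were seen. No named gene turned its direction, but the balance of calls did: more were lower than higher in green against WT with DESeq2, the compared groups alone or WT replicate 3 left out (46 and 57), and at V9 with DESeq2 or WT replicate 2 left out (29 and 139). In endosperm more were higher than lower with DESeq2, library size alone (5 and 4), no filter, all 21 libraries (8 and 6), and WT replicate 2 (4 and 2) or zb10 replicate 1 (13 and 5) left out; more were lower with the block (2 and 4) and with zb10 replicate 2 (4 and 7), zb10 replicate 3 (3 and 4) or WT replicate 1 (0 and 1) left out. Of calls for V9 minus green, 0% were higher, against 39.8% with DESeq2, 60% with RLE scaling and 100% (1 gene) with library size alone. Under the alternatives, 136 counts stayed within 1.5 times, 36 rose and 40 fell beyond that; 552 values of single genes kept their side of the threshold, 5 gained and 59 lost it, and of call counts within gene groups 131 stayed within 1.5 times, 13 rose and 40 fell. With library size alone 2455 genes were lower in white against WT and 1613 in white against green. DESeq2 gave 419 higher and 455 lower for green against WT, 90 and 140 at V9, 64 and 53 in endosperm, 309 for V9 minus green and 191 for endosperm minus V9. For V9 minus green, RLE scaling gave 5, no filter 9 and a mean of 1 CPM 10. Without the filter, V9 gave 16 and 8, and endosperm 13 and 11. All 21 libraries in the fit gave 48 and 29 for green, 46 and 18 at V9, 8 higher in endosperm, 6 for V9 minus green and 23 for endosperm minus V9. The compared groups alone gave 218 and 275 for green. The trace term gave 1 and 1 in endosperm. The cause of these changes was not tested, except that filters change the genes tested.

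Same-number correlations gave no clear pairing of the WT and zb10 libraries: 0.34, 0.12 and -0.19 at V9 and -0.03, -0.06 and 0.12 in endosperm. They cannot show that these libraries were unmatched, and the labels only number the samples. With the replicate block V9 gave 2 and 1, endosperm 2 higher, V9 minus green 3 and endosperm minus V9 4. The block kept all V4 counts within 1.5 times, with 3562 and 3127 for the 2 sections alone.

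Leaving out 1 library gave 28 to 62 higher and 16 to 57 lower for green, 1908 to 2636 lower for white against green, 5 to 29 and 0 to 139 at V9, 0 to 13 and 0 to 7 in endosperm. The interaction counts ranged from 0 to 157 for V9 minus green, 2041 to 3916 for V9 minus white and 8 to 20 for endosperm minus V9. White against WT ranged from 3321 to 4043 and 2702 to 3666. WT V9 replicate 2 gives the highest V9 values. Among log2 fold changes of called genes, Zm00001d042453 went to 12.24 (white) and 12.29 (green) without WT V4 replicate 2 and to 9.23 and 10.80 at V9 without WT replicate 1 and 2, Zea_mays_newGene_19853 to 7.24 and 7.51 without WT V4 replicate 1, and Zm00001d028750 to 15.11 and 9.46 without green replicate 1 and 3, with each call kept. Without green replicate 1 the green group of Zm00001d028750 had 0 counts, so 15.11 is a fitted value over 0 and not a measured fold. Zm00001d003494 went to -7.58 without white replicate 3 and Zm00001d015053 to -3.63 without white replicate 2. In simulations with 200 changed genes at these depths and spreads, 51% of 2-fold changes were recovered at V4 (white against WT) and 17% at V9. Many more genes were called in the real white section, so 51% need not hold there.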

Other observations

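The simulation of an unchanged green section was chosen after the result was seen. Of 4465 genes higher in white than in WT, the green value lay between both for 71.6%, and of 3985 lower for 77.8%; both comparisons share the WT libraries, which alone places green values between. With green simulated as unchanged from WT and white with its fitted log2 changes, the shares were 55.5% and 57.2% (means of 20 simulations), and with those changes halved 63.2% and 69.4%, at most 68.1% and 72.9% in any simulation. The correlated deviations of white and green sections with the same number were not simulated, and their effect on these shares was not measured, so whether green values were intermediate stays open.

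Zm00001d001909 was lower in every zb10 leaf library than in every WT leaf library, and at 5.92 to 10.2 CPM in zb10 endosperm against 15.5 to 19.0 in WT. The endosperm difference passed with DESeq2 (adjusted p = 0.0015) and with all 21 libraries in the edgeR fit (adjusted p = 0.011), and not in the edgeR fit of endosperm alone (adjusted p = 0.34), over a range of 0.0015 to 0.84 among alternatives. Zm00001d042453 was at 610, 0 and 410 CPM in the zb10 endosperm libraries and at 0.213 CPM or less in WT.

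Traces of abundant endosperm transcripts (27 genes) reached 6.38 to 43.8 CPM in the V9 leaf libraries and 0.504 or less in the V4 leaf libraries. WT V9 replicate 2 had the highest value. No biological explanation was tested.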
